A study of Rattus norvegicus with 4 samples.

How the data were processed

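Circular RNAs (circRNAs), transcripts closed by a back-splice that joins a downstream splice site to an upstream one, were measured by total RNA sequencing of rat sciatic nerve. The 4 libraries were 2 from crushed nerves and 2 from sham-operated nerves, taken 24 h after surgery. Per the labels' protocols, RNA was extracted with an RNeasy column kit and made into paired-end libraries with the VAHTS total RNA kit. The submitters' processing notes name CASAVA 1.8, BWA, edgeR and the rat genome build Rnor_6.0, without saying at which step each was used. The program that called the circRNAs is not given in the sources used here.

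Per the file headers, the authors deposited for each library the back-splice junction read counts of every circRNA, as raw counts, and the same reads as SRPBM, a signal commonly read as spliced reads scaled to the mapped reads of the library. Within a library the deposited SRPBM signal was the junction read count times 1 constant, so it held no information beyond the count and a library total. A single read was worth 0.0725 and 0.0598 SRPBM in crush replicates 1 and 2, and 0.0729 and 0.0786 in sham replicates 1 and 2. Whether the total behind it counts reads or bases is not given in the sources used here. All 4 files listed the same 4942 circRNAs, on chromosomes 1 to 20, X and Y, with position, strand, class and host gene. A listed count was 0 or at least 2, so a 0 stands for a circRNA that the caller did not report in that library, which can hide reads. The deposited genomic length equalled end minus start for all 4942 circRNAs. It is called span below, it includes introns and it is not the length of the circular molecule. Coordinates are those of the files, in Rnor_6.0, and their base convention was not stated.

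The files classed 3731 circRNAs as exonic, 479 as intronic and 732 as intergenic. Host genes came from the files as an Ensembl identifier and a symbol. Of 2327 host genes, 2174 symbols matched a current symbol of the RefSeq gene table for the assembly GRCr8, 99 matched through a synonym, and 54 were kept as the files gave them. That table served for names only. The 3 circRNAs with 2 host genes stayed out of host gene sums.

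The main test was edgeR 4.0.16's quasi-likelihood test (glmQLFit and glmQLFTest) in R 4.3.3, on the deposited counts with TMM scaling over all 4 libraries, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. CircRNAs with at least 5 junction reads in at least 2 libraries were tested. Host genes were tested the same way on junction reads summed over their circRNAs. TMM scaling of junction reads removes any shift common to all circRNAs. Fixed gene lists with at least 5 tested members were tested with limma 3.58.1's camera at a preset correlation of 0.01, on log2 CPM with a prior count of 2, adjusted over the lists. The 15 lists, the tests, the rule for named genes and the alternatives not said to be added were fixed before the data were examined. Sums of junction reads over all members of a list, fitted as added entries of the host gene model, were chosen after seeing the data. Single measures per library were compared with an exact permutation test, whose smallest p for 2 against 2 is 0.333.

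Where both libraries of a group were listed at 0, the fold is given as a lower bound in SRPBM, against a floor of 3 reads in each library at 0. Such a bound holds only where a listed 0 means few reads. Shares have 95% exact Clopper-Pearson intervals. Intervals and floors cover counting error only. Values in SRPBM are mean ± SD with n = 2, and log2 changes are crush minus sham with the standard error of the model. SRPBM means and bounds do not use the TMM scaling of the model, so their ratios differ from its log2 changes and folds. Library totals from the SRPBM constants moved the median log2 change of tested circRNAs from 0.03 to -0.37. Bounds are therefore larger for falls and smaller for rises than they would be on the TMM scale.

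The named circRNAs are the 12 per direction with the smallest p among those past the threshold whose crush libraries both lay on one side of both sham libraries. The named host genes are the 8 per direction by the same rule, and where fewer than 6 passed, the 6 with the smallest p are given and said not to pass. The 8 most abundant circRNAs and, for each list, the 4 members with the highest mean level plus any member past the host gene test complete the rule. One list member that the rule names is not reported here. The labels do not say whether the 2 libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

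Before use, the tests of circRNAs, host genes, fixed lists and circRNAs of 1 host were run on simulated counts with known changes, in 10 simulations. Counts were drawn from the real means and library sizes. The test of list sums, Fisher's exact test and the slopes on span were not simulated. The simulated counts had 1 common dispersion and no excess of listed zeros. The deposited counts had such an excess, described below, so the rates of recovered and of false calls may not hold for them. At the circRNA level the main test recovered 13.1% of 4-fold and 78.0% of 16-fold changes over a mean of 424 circRNAs tested, and 0.569% of its calls were false. At the host gene level it recovered 29.9% of 4-fold and 93.4% of 16-fold changes over a mean of 421 host genes tested, with 1.00% of calls false. Camera found 10 of 10 changed lists, camera with an estimated correlation found 0 and fry found 3. In these lists every member rose 4-fold and members varied independently, which suits the preset correlation. The simulation does not show how camera behaves for genes that vary together.

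The alternatives were other scalings, other filters on low counts, DESeq2 1.42.0, edgeR's exact test, the replicate number as a block, and leaving out each library. With a library left out, 1 group holds a single library, so the spread behind those p-values comes from the other group alone. Added after seeing the data were library totals from the SRPBM constants, only circRNAs or host genes called in all 4 libraries, and crossed replicate numbers. A planned comparison of circular with linear reads was not analysed here because the files used held junction reads only. Counts after thinning to 8250 reads are means of 100 draws. Descriptive measures used Python 3.11.15 with scipy 1.17.1.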

Results

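Total RNA of the sciatic nerve of Sprague-Dawley rats at postnatal week 6 was sequenced for circRNAs. In the crush group, 3 mm of nerve was crushed 2 times for 15 s with 3 s between, and in the sham group the nerve was only exposed. The crushed segment with 1 mm of nerve at both ends was taken 24 h after surgery. There were 2 libraries per group, with 8250 and 9027 back-splice junction reads in crush replicates 1 and 2, and 9018 and 8726 in sham replicates 1 and 2. The comparison asks which circRNAs of the nerve differ in level 24 h after injury, when axons distal to a crush begin to break down and leukocytes enter the nerve.

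Crushed and sham nerve had similar totals of junction reads, spread differently over circRNAs. The 10 most abundant circRNAs of each library took 8.40% and 8.16% of the junction reads after crush and 15.6% and 15.6% after sham. The caller reported 1785 and 2022 circRNAs in the crush libraries and 1704 and 1711 in the sham libraries, or 1785, 1862, 1588 and 1630 after thinning all libraries to the depth of the shallowest. In SRPBM, the total was 569 ± 41.3 after crush and 672 ± 20.7 after sham (SD, n = 2), a difference of -15.3%. The exact permutation p was 0.333 for each of the share, the number and the SRPBM total, the smallest that 2 against 2 can give. With at least 5 reads required, the mean number was 431 after crush and 433.5 after sham, so the excess after crush lay among circRNAs with few reads.

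Most circRNAs were seen in a single library. Of the 4942 circRNAs, 3587 (72.6%) were called in 1 library and 303 in all 4. Both crush libraries and no sham library had 223, and both sham libraries and no crush library had 176. Exonic circRNAs took 75.1% (95% interval 74.2% to 76.1%) and 75.2% (74.3% to 76.1%) of junction reads after crush and 74.8% (73.9% to 75.7%) and 76.2% (75.3% to 77.1%) after sham. The exonic share differed by less than the spread between the sham replicates. Ash1l, a histone methyltransferase gene, gave the most circRNAs, with 16, followed by Evi5 and Picalm with 14 each, and by Utrn, Dennd4a, Atrnl1 and Vps13a with 13 each.

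The most abundant circRNA came from exonic sequence of Nfix (ENSRNOG00000002983), a gene for a nuclear factor I transcription factor, at chromosome 19, 25886356 to 25886887. It had 67 and 106 reads after crush against 265 and 340 after sham, a log2 change of -1.60 ± 0.39 (SE) that did not pass the circRNA test (adjusted p = 0.0615, edgeR). Exonic circRNAs of Mlip (chromosome 8, 84434784 to 84461546), which encodes a lamin-interacting protein of muscle, and of Ttc3 (chromosome 11, 34612627 to 34614139), which encodes a ubiquitin ligase, had log2 changes of -1.24 ± 0.31 and -1.33 ± 0.33, both with adjusted p = 0.0638. The exonic circRNA of Spidr (chromosome 11, 89175425 to 89180448), a DNA repair gene, had 47 and 80 reads against 74 and 82. The exonic circRNA of Arid1a (chromosome 5, 151944769 to 151947717), a subunit of the SWI/SNF chromatin remodelling complex, had 64 and 88 reads after crush and 0 and 44 after sham, and its adjusted p was 0.502. Among abundant circRNAs classed as intergenic, that at chromosome 3, 81127393 to 81143240, had 151 and 102 reads against 111 and 107 (adjusted p = 0.508) and shared an end with a circRNA of Phf21a. Another at chromosome 10, 62623758 to 62664462, had 34 and 80 against 62 and 93 (adjusted p = 0.849).

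After crush, 32 circRNAs rose and 19 fell out of 428 tested (edgeR quasi-likelihood test, adjusted p under 0.05). Of the 32, 18 were exonic, 3 intronic and 11 intergenic, and 28 were listed at 0 in both sham libraries. Of the 19, 14 were exonic and 5 intergenic, and 16 were listed at 0 in both crush libraries. Among all 428 tested circRNAs, 61 were listed at 0 in both libraries of a group. Of these 61, 44 were among the 51 calls, so most calls were circRNAs listed at 0 in a whole group. A listed 0 also occurred between replicates, in 18 of 188 cases of a circRNA with at least 20 reads in the other library of its group. The circRNA of Emilin2, a gene for an elastin-associated matrix glycoprotein, rose 9.16-fold, and the circRNA of Crebrf, a regulator of the CREB3 pathway, fell 5.16-fold. The most abundant circRNA to pass was an intergenic one on chromosome 10, and it fell 6.87-fold.

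The circRNA of Emilin2 (chromosome 9, 119615345 to 119617261, exonic) had 58 and 63 reads after crush against 6 and 9 after sham, or 3.99 ± 0.31 against 0.572 ± 0.191 SRPBM, a log2 change of 3.19 ± 0.45 (adjusted p = 0.0454). An intergenic circRNA at chromosome 4, 168514863 to 168517342, with 15514 bases to the nearest circRNA of Dusp16 on the same strand, had 64 and 37 reads against 8 and 4, a log2 change of 3.28 ± 0.56 (adjusted p = 0.0454, edgeR). It shared an end with another tested intergenic circRNA of that strand, 168499186 to 168517342, which overlapped a circRNA of Dusp16. The other 10 named circRNAs that rose were listed at 0 in both sham libraries, each with adjusted p = 0.0454. That of Upf2 (chromosome 17, 76245627 to 76265943, exonic), a factor of nonsense-mediated decay, had 26 and 29 reads, at least 7.96-fold higher. That of Cers6 (chromosome 3, 55157605 to 55224851, exonic), a ceramide synthase gene, had 30 and 22 reads, at least 7.68-fold higher. That of Dgkh (chromosome 15, 60892679 to 60895084, exonic), a diacylglycerol kinase gene, had 24 and 20 reads, at least 6.46-fold higher. That of Mgam (chromosome 4, 68943985 to 68971758, intronic), a maltase-glucoamylase gene with close relatives that make the host uncertain, had 23 and 21 reads, at least 6.43-fold higher. That of Dot1l (chromosome 7, 11808382 to 11817191, exonic), a histone H3 lysine methyltransferase gene, had 5 and 6 reads, at least 1.59-fold higher.

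Intergenic circRNAs listed at 0 in both sham libraries included the one with the smallest p, at chromosome 1, 221185801 to 221186464, with 35 and 37 reads after crush, at least 10.5-fold higher. The intergenic circRNA at chromosome 1, 63736954 to 63760774, had 22 and 19 reads, at least 6.01-fold higher, and overlapped circRNAs of Lilrb3l, a gene of the leukocyte immunoglobulin-like receptors, whose members are similar enough to leave the origin uncertain. The intergenic circRNA at chromosome 10, 91244105 to 91244498, had 21 and 14 reads, at least 5.19-fold higher. Those at chromosome X, 119208336 to 119210714, and chromosome 16, 19805426 to 19805902, had 5 and 5 and 5 and 6 reads, at least 1.46-fold and 1.59-fold higher. Without a filter on low counts their adjusted p was 0.635 and 0.452, and that of the Dot1l circRNA was 0.452 (edgeR). Of 80 intergenic circRNAs tested, 20 overlapped a circRNA of a host gene on the same strand and 10 shared an end with one.

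Among circRNAs that fell, the exonic one of Crebrf (chromosome 10, 16724062 to 16730140) had 6 and 7 reads after crush and 40 and 39 after sham, or 0.427 ± 0.012 against 2.99 ± 0.11 SRPBM, a log2 change of -2.37 ± 0.42 (adjusted p = 0.0454). The intergenic circRNA at chromosome 10, 94083626 to 94187819, had 21 and 40 reads after crush and 206 and 277 after sham, a log2 change of -2.78 ± 0.47 (adjusted p = 0.0454), and the nearest circRNA of a host gene on its strand lay 104874 bases away, in Map3k3. A second intergenic circRNA of chromosome 10, 53632921 to 53787097, had 0 and 0 reads against 17 and 30, at least 9.07-fold lower after crush, and overlapped a circRNA of the skeletal muscle myosin gene Myh1, which has near-identical neighbours, so its origin is uncertain. Exonic circRNAs of Arhgef11 (chromosome 2, 187048486 to 187051162), Ranbp17 (chromosome 10, 18218676 to 18238682) and Rps6ka3 (chromosome X, 37523957 to 37537375) each had 5 and 5 reads after sham and 0 after crush, at least 1.91-fold lower. Ranbp17 encodes a nuclear transport receptor and Rps6ka3 a ribosomal S6 kinase. Exonic circRNAs of Arhgap10, Ankib1, Epb41l3, Bnc2 and Rgs3 and an intergenic one at chromosome X, 137706330 to 137733342, had 5 to 7 reads in each sham library and 0 after crush, with adjusted p from 0.0454 to 0.0474 and folds of at least 2.09 to at least 2.47. Without a filter on low counts, these and the circRNAs of Arhgef11, Ranbp17 and Rps6ka3 had adjusted p from 0.354 to 0.635 (edgeR). The abundant intergenic one at 94083626 to 94187819 then had 0.635 too. That of Crebrf (adjusted p = 0.0253) and the intergenic one at 53632921 to 53787097 (adjusted p = 2.66e-09) still passed.

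The adjusted p of the 51 calls lay just under the threshold, and 119 circRNAs had an unadjusted p under 0.05. None of the 51 passed when circRNAs with at least 2 reads in 2 libraries were tested, where 434 of 1355 had an unadjusted p under 0.05, and 6 circRNAs passed without crush replicate 1, 6 without crush replicate 2 and 76 without sham replicate 1. With 1 crush library left out, only 22 of the 51 calls had enough reads to be tested, and 35 with 1 sham library left out. Calls left untested are not calls that lost significance, but they are only part of the drop. Most of the 22 calls that were tested without either crush library also missed the threshold. With library totals from the SRPBM constants, 31 circRNAs rose and 28 fell (52.5% higher, against 62.7%), since these totals move the median log2 change of all tested circRNAs from 0.03 to -0.37.

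Summed per host gene, junction reads of 8 genes rose and those of 2 fell out of 434 tested (edgeR quasi-likelihood test, adjusted p under 0.05). The 8 were Cers6, Dgkh, Emilin2, Klhl21, Mgam, Vcan, Sdcbp and Csf3r, and 7 of them, all but Emilin2, were listed at 0 in both sham libraries. The 2 that fell were Nfix, by 3.10-fold, and Ttc3, by 2.56-fold, both among the hosts with the most junction reads in sham nerve. The genes that rose include those of a neutrophil growth factor receptor (Csf3r), a large chondroitin sulfate proteoglycan of the matrix (Vcan) and the adaptor protein syntenin (Sdcbp).

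Cers6 had 49 and 39 reads after crush over 6 circRNAs, at least 12.9-fold higher (adjusted p = 0.0358). Dgkh had 34 and 32 reads over 7 circRNAs, at least 9.63-fold higher (adjusted p = 0.0358). Klhl21, a gene for a cullin adaptor used in cell division, had 22 and 51 reads over 8 circRNAs, at least 10.2-fold higher (adjusted p = 0.0445). Emilin2 had 58 and 67 reads against 6 and 9, a log2 change of 3.24 ± 0.44 (adjusted p = 0.0358). Vcan had 15 and 27 reads, Sdcbp 15 and 25, and Csf3r 28 and 16, each with adjusted p = 0.0490 and at least 5.94-fold, 5.68-fold and 6.57-fold higher. Mgam, with 1 circRNA, had the values given for it above and adjusted p = 0.0445.

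Nfix had 67 and 106 reads after crush against 265 and 348 after sham, or 5.60 ± 1.05 against 23.3 ± 5.70 SRPBM, a log2 change of -1.63 ± 0.29 (adjusted p = 0.0490). Ttc3 had 61 and 79 against 230 and 186, over 10 circRNAs, or 4.57 ± 0.21 against 15.7 ± 1.50 SRPBM, a log2 change of -1.36 ± 0.24 (adjusted p = 0.0490). The next 4 by p among hosts lower after crush did not pass. Mlip had 76 and 79 reads against 204 and 226 (adjusted p = 0.0522). Stk39, a kinase gene of ion transport control, had 8 and 9 against 58 and 38 (adjusted p = 0.0558). Prex2, a Rac exchange factor gene, had 0 and 0 against 15 and 17 (adjusted p = 0.0558). Lifr, the gene of the receptor for leukemia inhibitory factor, had 7 and 14 against 71 and 48 (adjusted p = 0.0567).

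At the host level 111 genes had an unadjusted p under 0.05. The number past the threshold was 0 without crush replicate 2, 0 with at least 2 reads in 2 libraries, 44 with at least 10, and 84 without sham replicate 2, and the adjusted p of Nfix and Ttc3 was 0.184 and 0.241 without crush replicate 1 and 0.178 for both without crush replicate 2. With 1 crush library left out, only 3 of the 10 host genes past the threshold had enough reads to be tested. With SRPBM totals 8 hosts rose and 6 fell (57.1% higher, against 80.0%), and the median log2 change moved from 0.11 to -0.30.

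**Figure D1:**
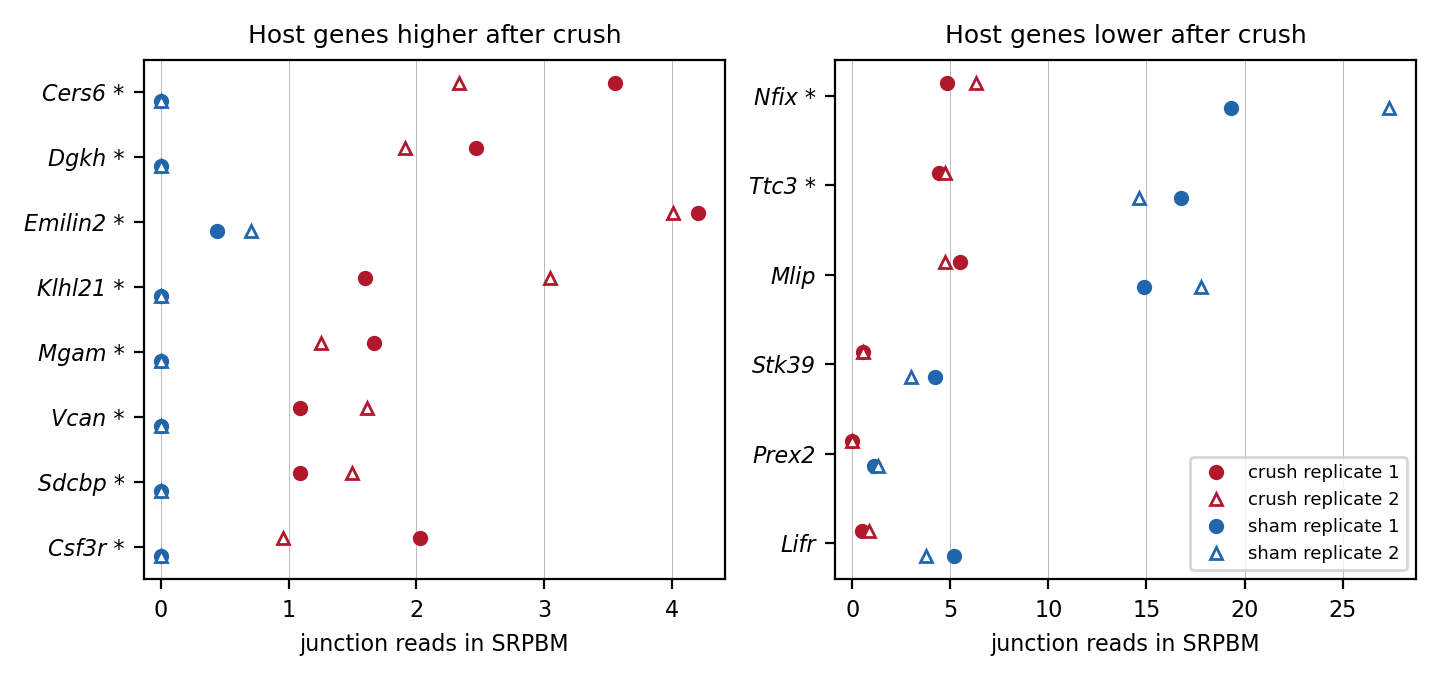
Junction reads in SRPBM (x axis) summed per host gene (y axis) for the host genes named by the fixed rule, 1 symbol per library (red, crush; blue, sham; filled circle, replicate 1; open triangle, replicate 2), with an asterisk on the 10 genes past the threshold. All 8 genes of the left panel lie higher in both crush libraries than in both sham libraries, 7 of them with both sham libraries at 0, and Nfix and Ttc3 in the right panel lie lower in both crush libraries.

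The summed junction reads of the leukocyte and inflammation list were higher after crush. Junction reads of the list's 24 detected hosts numbered 125 and 144 after crush against 21 and 16 after sham, or 8.84 ± 0.32 against 1.39 ± 0.19 SRPBM (SD, n = 2). All 8 members tested were higher, and camera gave adjusted p = 5.57e-05 over the 6 lists with enough tested members. With an estimated correlation the adjusted p = 0.261, and fry gave adjusted p = 0.00143. Of the 8, Csf3r alone passed over all genes, and 7 passed adjusted over the list alone.

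Csf3r, Syk (13 and 12 reads), Dock8 (8 and 12), Arhgap15 (10 and 7), Nampt (7 and 8) and the integrin alpha M gene Itgam (6 and 5) had no reads called in either sham library. Syk encodes a kinase of immune receptors and Dock8 an exchange factor of leukocyte migration. Picalm, a clathrin assembly gene expressed in many tissues and the 1 detected member that another list also holds, had 23 and 36 reads against 12 and 9, a log2 change of 1.69 ± 0.48 (adjusted p = 0.0836), and Mctp1 had 7 and 9 against 3 and 3 (adjusted p = 0.248). Without Picalm the list had 102 and 108 reads against 9 and 7. The fitted median log2 change of the 8 was 6.13, and 1.55 with the 6 members at 0 in sham set to their bounds. The sum of the list rose by a log2 of 3.07 ± 0.33 (adjusted p = 0.000626 over 15 list sums). It was 2.85 to 3.23 when any 1 library was left out. Camera could not test the list without either crush library, since fewer than 5 members then had enough reads.

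No other list passed camera on host reads of all 4 libraries under the reported filter. Without crush replicate 2 the RNA-binding list passed as higher and the cytoskeleton list as lower (adjusted p = 0.0473 for each). The lists of chromatin regulators (12 of 15 tested members higher, adjusted p = 0.445), ubiquitin ligases (10 of 16, adjusted p = 0.532), RNA-binding factors (6 of 8, adjusted p = 0.445) and widely reported circRNA hosts (13 of 22, adjusted p = 0.532) had more tested members higher than lower, and the cytoskeleton list had more lower than higher (9 of 11, adjusted p = 0.274). In the RNA-binding list, Upf2 had 40 and 46 reads against 8 and 2 (adjusted p = 0.0522 over all genes, 0.0125 adjusted over the list alone), Cnot6l, a deadenylase gene, had 46 and 24 against 13 and 11 (adjusted p = 0.0860), Larp1b 17 and 7 against 16 and 11, and Cnot2 9 and 20 against 6 and 7. This list passed fry (adjusted p = 0.0417). In the chromatin list, Ash1l had 58 and 68 reads against 64 and 57, Arid1a 68 and 96 against 0 and 44, Kmt2e 36 and 28 against 11 and 40, and Tet3, a gene of DNA demethylation, 16 and 38 against 4 and 11 (adjusted p = 0.133). In the ubiquitin list, Usp32 had 28 and 17 reads against 21 and 9, Herc1 6 and 13 against 28 and 21, and Rnf169 21 and 24 against 15 and 5. By sums, these 3 lists were higher after crush, with log2 changes of 1.07 ± 0.27, 0.80 ± 0.24 and 0.99 ± 0.28 for the RNA-binding, chromatin and ubiquitin lists (adjusted p = 0.0285, 0.0373 and 0.0373, edgeR). With SRPBM totals none of the 3 passed (adjusted p = 0.126, 0.244 and 0.174, edgeR). The chromatin sum includes Arid1a and Kmt2e, which each had an abundant circRNA listed at 0 in sham replicate 1. Its log2 change was 0.42 without that library. All 3 sums also missed the threshold without crush replicate 1 (adjusted p = 0.115, 0.129 and 0.261) and without crush replicate 2 (0.103, 0.166 and 0.0835), and the RNA-binding and chromatin sums without sham replicate 1 (0.0548 and 0.170).

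Among widely reported circRNA hosts, Nfix passed over all genes and 2 members passed adjusted over the list alone. Spidr had 49 and 93 reads against 82 and 98, Pan3 79 and 79 against 50 and 66, and Hipk3, host of a circRNA known in many tissues, 24 and 36 against 28 and 30. The signs differed for this list, with a median log2 change of 0.45 over members and -0.35 ± 0.21 for the sum (adjusted p = 0.189, edgeR). The sum was lower with SRPBM totals (adjusted p = 0.0252, edgeR), and its log2 change was -0.69 without sham replicate 1. Nfix alone gave 67 and 106 of the list's 406 and 534 reads after crush. After sham it gave 265 and 348 of 624 and 748, so the lower sum rests largely on Nfix. In the cytoskeleton list, Arhgap10 had 7 and 20 reads against 27 and 50 (adjusted p = 0.237), Arhgap32 2 and 13 against 23 and 43 (adjusted p = 0.190), Myo9a 12 and 15 against 18 and 14, and Utrn 4 and 9 against 11 and 16. Tested by camera on single circRNAs in place of hosts, the cytoskeleton list was lower (adjusted p = 0.00649). Arhgap10 and Arhgap32 gave 3 each of its 10 entries. The preset correlation of 0.01 treats circRNAs of 1 host as nearly independent, so this p may be too small. By sums, it had a log2 change of -0.60 ± 0.30 (adjusted p = 0.155; 0.0291 with SRPBM totals and 0.0372 without sham replicate 1).

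Lists of nerve cell types had few reads. The perineurial and nerve barrier list had 3 and 4 reads after crush against 26 and 20 after sham, and its sum fell by 2.46 ± 0.55 on the log2 scale (adjusted p = 0.0247; 0.0835 without crush replicate 2). Its reads came mainly from Tenm2, a teneurin adhesion gene (3 and 4 against 18 and 9), with Gli3 (0 and 0 against 2 and 6) and Ptch1 (0 and 0 against 3 and 3), of hedgehog signalling, and the tight junction gene Tjp1 (3 reads in sham replicate 1 alone). The myelin and Schwann cell list had 23 and 28 reads against 49 and 64, a sum log2 change of -0.94 ± 0.39 that did not pass (adjusted p = 0.104; -1.36 and 0.0307 with SRPBM totals, 0.0394 without sham replicate 1). Of its members, Utrn had the counts above, Sbf2, a gene of an inherited neuropathy, had 6 and 4 against 14 and 11, Ugt8, of myelin lipid synthesis, 4 and 4 against 8 and 7, and Dst 2 and 3 against 0 and 17. The repair Schwann cell list had 12 and 19 reads against 7 and 10 (sum log2 change 1.05 ± 0.55, adjusted p = 0.155), with Fosl2 at 0 and 9 against 4 and 0, Zeb2 at 5 and 0 against 3 and 2, Nrg1 at 2 and 3 against 0 and 5, and Cd44 at 5 and 3 against 0 and 0. The cell cycle list had 20 and 35 against 7 and 13 (1.64 ± 0.56, adjusted p = 0.0575; 0.0131 without crush replicate 1 and 0.0140 without sham replicate 2), with the kinetochore gene Casc5 at 0 and 8 against 4 and 2, Brca1 at 3 and 5 against 3 and 2, Atad2 at 3 and 6 against 0 and 0, and the kinase gene Melk at 3 and 5 against 0 and 0.

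The matrix and fibroblast list had 25 and 51 reads against 22 and 25 (0.88 ± 0.47, adjusted p = 0.155). Vcan rose within it. The laminin gene Lama2 had 0 and 2 against 7 and 8 (adjusted p = 0.237), Ltbp1 2 and 2 against 2 and 5, and Itga1 2 and 4 against 0 and 5. The endothelial and mural list had 15 and 10 against 13 and 24 (-0.35 ± 0.57, adjusted p = 0.640), with Flt1, a receptor for vascular endothelial growth factor, at 8 and 8 against 4 and 4, Dysf at 2 and 0 against 4 and 7, Tll1 at 2 and 2 against 2 and 4, and Tek at 0 and 0 against 3 and 3. Lists of other tissues and cells did not pass. Skeletal muscle had 7 and 20 reads against 12 and 31 (-0.50 ± 0.70, adjusted p = 0.629), with Pdlim5 at 7 and 7 against 0 and 7, Asph at 0 and 8 against 4 and 9, Mybpc2 at 0 and 0 against 2 and 6, and Myh1 at 0 and 0 against 3 and 5. Adipocyte genes had 5 and 6 against 9 and 2 (0.23 ± 0.92, adjusted p = 0.813), with Pde3b at 0 and 2 against 7 and 0, Acly at 3 and 2 against 0 and 2, Prkar2b at 2 and 0 against 0 and 0, and Pparg at 0 and 0 against 2 and 0. Neuronal genes had 20 and 15 against 18 and 17 (0.22 ± 0.47, adjusted p = 0.704), with Homer1 at 16 and 12 against 12 and 7, Rims2 at 0 and 0 against 4 and 5, Scn10a at 2 and 0 against 2 and 3, and Dclk1 at 2 and 3 against 0 and 0.

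**Figure D2:**
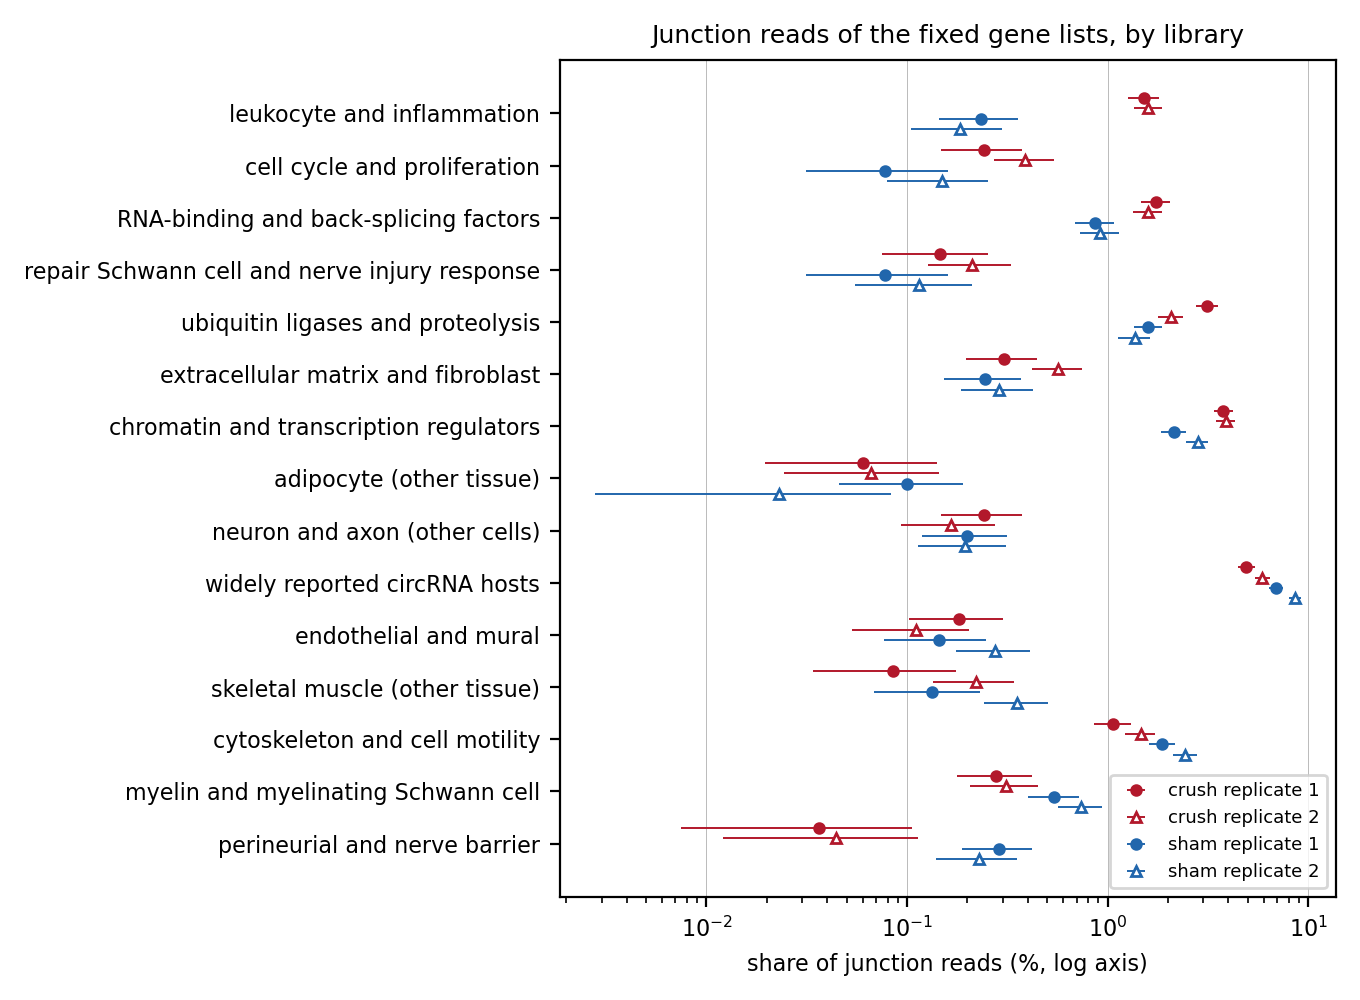
Share of each library's junction reads (x axis, percent, log axis) that came from host genes of the 15 fixed lists (y axis), with 95% exact binomial intervals that cover counting error only (red, crush; blue, sham; filled circle, replicate 1; open triangle, replicate 2). The leukocyte list took 1.52% and 1.60% after crush against 0.233% and 0.183% after sham, and the perineurial list 0.0364% and 0.0443% against 0.288% and 0.229%.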

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

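The number of calls moved with the processing. No named circRNA or host changed direction, but this was largely fixed by their choice. All of them had both crush libraries on one side of both sham libraries, and many had a whole group at 0. Alternatives added after seeing the data were the SRPBM totals, calls in all 4 libraries, crossed numbers and list sums. Among named circRNAs 179 values kept direction and side of the threshold and 109 kept direction alone, and among named hosts 138, 25 and 37 did the first, the second or passed only under the alternative. Against 51 circRNAs, 23 passed with at least 10 reads and 23 with filterByExpr, where fewer were tested (18 and 19 shared with the 51), 0 with at least 2 reads (434 at unadjusted p under 0.05), 30 with DESeq2 (18 shared), which gave no adjusted p to 100, 98 with edgeR's exact test (51 shared), and 29 among those called in all 4 libraries (7 shared). With no filter 52 of 4942 passed, of which 17 were among the 51. Against 10 hosts, these gave 44, 44, 0 (293 unadjusted), 32, 88 and 17, and no filter gave 39. Leaving out 1 library gave 6 to 76 circRNAs, 0 to 84 hosts and 0 to 2 lists. With 1 crush library left out, 22 of the 51 circRNAs and 3 of the 10 hosts still had enough reads to be tested. With the replicate number as a block, 0 circRNAs (53 unadjusted) and 24 hosts passed, and 0 and 0 with the numbers crossed (62 and 46 unadjusted). Deviations of same-numbered libraries had r = -0.11 and rho = 0.02 across 428 circRNAs. With 1 difference per group, this cannot exclude that same-numbered libraries share more than a number. The 24 hosts with the block against 0 with crossed numbers also leave this open. The block changed no list call. Against 1 list by camera, 0 passed with an estimated correlation, 2 with fry, 0 with at least 10 reads (the leukocyte list then had too few members), 2 on circRNAs and 5 by list sums. The excess of detected circRNAs after crush turned to -2.5 with at least 5 reads and -6.5 with at least 10. The exonic share, -0.328 points after crush, was -3.25 as a share of circRNAs, 1.23 with at least 5 reads and -1.01 to 0.357 without 1 library, the last without sham replicate 2. Where no reason is given, the cause was not tested. No alternative with junction plus linear reads, with pseudocounts or with a batch was run, since the files used held none of these. At this depth of 8250 to 9027 junction reads and with 2 libraries per group, simulated 4-fold changes of circRNAs were recovered in 13.1% of cases and 16-fold ones in 78.0%. The simulated counts lacked the excess of listed zeros described below.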

Other observations

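The tests on junctions listed at 0, on the leukocyte list, on other splits and on circRNAs of 1 host were chosen after their results were seen, and those on span after the trend was noticed and before their own results.

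Whether circRNAs of 1 host change apart was tested where several had enough reads. Over 52 hosts with at least 2 tested circRNAs, edgeR's diffSpliceDGE with Simes' method found 0 hosts whose circRNAs changed apart (smallest adjusted p = 0.541, 3 hosts at an unadjusted p under 0.05), and in simulation it recovered 28.5% of 16-fold changes, so the hypothesis stays open. Beyond the named circRNAs, those past the threshold included, by choice after their values were seen, circRNAs of Tnfaip3, a brake on NF-kB signalling (5 and 6 reads after crush, 0 and 0 after sham), of Sirpa, a receptor of myeloid cells (6 and 5 against 0 and 0), 2 of Syk (7 and 7, 6 and 5, against 0 and 0), and of Ppp3cc, a calcineurin subunit gene (0 and 0 after crush, 21 and 12 after sham).

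The other 2 splits of the 4 libraries into pairs gave at most 0 circRNAs and 0 hosts against 51 and 10 for the real one, so 1 of 3 splits gave as many at each level, and 3 splits are too few for a share under 0.05.

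Abundant circRNAs were at times listed at 0 in 1 library of a group. Of 188 cases of a circRNA with at least 20 reads in a library, 18 were at 0 in the other library of the group, where a negative binomial with the fitted dispersion gives 0.167 (upper bound 1), which argues against counting noise and usual replicate spread. Those at 0 had in 0 cases a call of at least 5 reads within 20 bases of both ends, which argues against reads given to a junction with nearly the same ends. In 4 cases, of Snx13, Arid1a, Pwwp2a and Irak3, the other 3 libraries all had at least 20 reads, and Ralgapa1 had 207 reads in sham replicate 1 alone. A candidate explanation is that the caller's own filters dropped these junctions, which stays open without the reads and would also bear on the 44 calls whose other group was at 0.

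The rise of the leukocyte list after crush may reflect leukocytes that entered the nerve or a rise in resident cells, and these cannot be told apart from these files: 5 of the 24 detected hosts were also called in a sham library, and no sorted cells were analysed here. Scaling is argued against, since the list's sum stayed 2.66 higher on the log2 scale with SRPBM totals. Junctions dropped by the caller without regard to host stay open: 9 list hosts were called in both crush and no sham library and 1 the reverse way, against 137 and 114 other hosts (Fisher's exact p = 0.0462, two-sided), but this counts the pattern that singled the list out. Library preparation that differed between the groups stays untested.

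CircRNAs of longer genomic span were lower after crush. The log2 change fell by 0.254 per doubling of span over 428 circRNAs (95% bootstrap interval over hosts -0.394 to -0.121; Spearman's rho = -0.183 across circRNAs, permutation p = 0.0004, circRNAs not being independent replicates). Over the 249 of these called in all 4 libraries the slope was -0.0743 (-0.154 to 0.0007), with Spearman's rho = -0.127 (permutation p = 0.0466). That choice drops the largest changes and so flattens any slope. Whether the trend comes from circRNAs listed at 0 in a whole group stays open. Over 328 exonic circRNAs under 100 kb the slope was -0.1235 (-0.270 to 0.018), with Spearman's rho = -0.098 (permutation p = 0.0698). Within 52 hosts the slope was 0.0149 (-0.259 to 0.212). Both intervals hold 0 and the slope over all 428, so long intergenic junctions and span itself within a host stay open.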
